A study of Mus musculus with 15 samples.

How the data were processed

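Total RNA from lung ILC2s was measured on 15 arrays, 1 per biological replicate as the labels call them. Per the labels' protocols, RNA was extracted with Trizol and labelled with biotin using the Nugen Encore kit. Effector adults received IL-33 into the nose on 3 days, with isolation 1 day after the last dose. The number of mice per replicate, the markers used to sort the cells, the sex of the neonates and any batches are not given in the sources used here.

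The values are log2 expression levels as deposited. Per the submitters' processing notes they were made with Affymetrix Expression Console and RMA, which corrects background, normalizes quantiles across arrays and summarises the probes of a feature on the log2 scale. Versions, annotation and filters of that step are not given in the sources used here. In the deposited table each array had similar quartiles and no negative value, as RMA output on a log2 scale has. The raw intensities were not used here. For arrays, the number of arrays limits the precision.

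The table held 41345 features, of which 25335 had an annotation. Exactly 1 gene symbol was given for 23521 features, several for 1814 and none for 16010. Features with several symbols or none were left out of the gene tests, because their signal cannot be assigned to 1 gene. Gene identifiers of 23328 features were found in a mouse gene table, which changed 0 symbols. A feature was kept when it lay above its array's percentile 40 in at least 3 arrays, as 28958 features did, 17153 of them with 1 symbol. Of several features of a gene, which 695 genes had, the one with the highest mean over all arrays was used. This left 16257 genes.

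The arrays were placed in 5 groups of 3. A linear model with a mean per group was fitted to all 15 arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (10 residual and 5.05 prior degrees of freedom). There were 8 comparisons: effector against naive adults over both sexes, in females and in males, the difference of these responses, females against males in naive and in effector cells, and neonates against naive and against effector adults with the sexes weighted equally. Tests were two-sided, p was adjusted over the 16257 genes by the method of Benjamini and Hochberg, and a gene was called at an adjusted p under 0.05. Errors given with log2 differences are the moderated standard errors of this fit to all 15 arrays. They do not show the spread within the groups compared, whose arrays are counted as n.

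Named genes were chosen by a fixed rule. They are the 6 largest rises and 6 largest falls among called genes whose groups did not overlap, unnamed gene models skipped; up to 4 called members with the largest change from each gene list, or up to 2 members where none was called; and Il5, Il13, Areg, Gata3, Il1rl1, Klrg1, Icos, Arg1 and Mki67. Not every gene that met the rule is printed. Areg and Il1rl1 had no feature with their symbol alone and were not tested.

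The 33 gene lists covered cytokines, receptors and regulators of ILC2s, proliferation, metabolism, stress and interferon responses, sex-linked genes, and markers of other cell types. Of 545 list entries 436 were tested, 51 fell below the filter and 58 had no feature with that symbol alone. Lists with at least 3 tested genes were compared with all other genes by limma's camera at a preset correlation of 0.01, and p was adjusted over the lists of a comparison. Camera with an estimated correlation and limma's fry were the alternatives. The neonatal and effector differences were compared by correlation, covariance and overlap, against 100 simulations of unchanged groups and with the naive arrays split between the comparisons.

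The pipeline was tested on simulated data with the same groups and number of arrays. Each gene was drawn independently, with a common spread for all groups. The real groups differ in spread and genes can vary together, so the rates below need not hold for the real comparisons or lists. With 100 genes moved by 1 log2 unit it recovered 78 for effector against naive adults, 51 to 68 for the other comparisons of groups and 14 for the difference of responses. With 100 genes moved by 2 log2 units it recovered 92 to 100 and, for the difference of responses, 71. Of 16257 genes, 3 to 17 were called falsely. For effector against naive adults, camera called 10 of 10 moved lists and 0 of 200 unmoved lists.

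Counts were recomputed without the dim filter and with it at percentile 60, after centring each array on its median, after a further quantile normalization, with a trended and robust prior, with array weights, with a replicate block, with only the arrays compared, with the mean of a gene's features, with a 2-fold threshold, and without each array in turn. Neonates were also compared with adults of each sex alone. Figures were drawn with matplotlib 3.10.9.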

Results

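Gene expression was measured in group 2 innate lymphoid cells (ILC2s) isolated from mouse lungs. ILC2s are tissue-resident lymphocytes without rearranged antigen receptors that secrete cytokines such as IL-5 and IL-13. The 15 Affymetrix arrays formed 5 groups of 3 biological replicates: naive adult females, naive adult males, effector adult females, effector adult males and neonates. Naive adults were 8 weeks old and neonates 10 days old. Effector cells came from adults that received IL-33, an epithelial cytokine that activates ILC2s, into the nose on 3 consecutive days, with isolation 1 day after the last dose. The labels gave no sex for the neonates. The design asks how ILC2s in the adult lung respond to IL-33, whether the sexes differ, and how neonatal cells compare with resting and activated adult cells. The number of arrays limits the precision of all values.

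The median level per array lay between 4.44 and 4.64 on the log2 scale. Arrays of a group correlated over all features at r = 0.965 to 0.974 in effector females and 0.962 to 0.969 in effector males, at 0.931 to 0.960 in naive females, 0.911 to 0.914 in naive males and 0.904 to 0.925 in neonates. The first principal component held 45.4% of the variance. Its mean score was -33.4 ± 1.83 (SD, n = 3) in naive females and -48.7 ± 9.56 (SD, n = 3) in naive males, -7.47 ± 13.4 (SD, n = 3) in neonates, 43.5 ± 5.81 (SD, n = 3) in effector females and 46.1 ± 3.78 (SD, n = 3) in effector males.

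**Figure D1:**
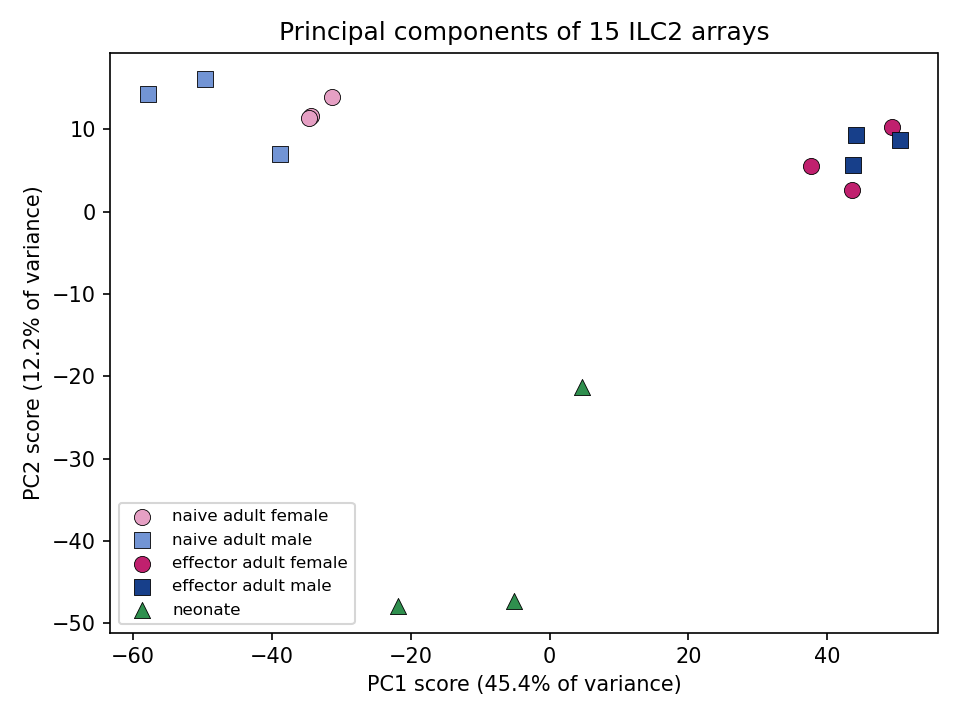
Scores of the 15 arrays on the first (horizontal) and second (vertical) principal components of the log2 levels of the tested genes; each point is 1 array, coloured by group. Effector arrays lie at the right, naive adult arrays at the left, and neonatal arrays between them on the first component, at mean scores of 43.5 and 46.1, -33.4 and -48.7, and -7.47.

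Many transcripts differed between effector and naive adult ILC2s. None of the 5 groups is labelled as dosed without IL-33, and the labels give no age for effector adults. Dosing itself, or a batch that follows the groups, thus cannot be told apart from IL-33. Rises and falls below are differences of effector from naive cells. Il1r2, the decoy receptor for IL-1, had the largest rise of the named genes, by 6.41 ± 0.32 on the log2 scale (SE, n = 6 effector and 6 naive arrays). Il13 rose by 3.07 ± 0.14 and Il5 by 1.46 ± 0.21, while Il2, the T cell growth factor gene, fell by 3.16 ± 0.27. The proliferation marker Mki67 rose by 4.87 ± 0.22. Gata3, the transcription factor on which ILC2 identity depends, differed by -0.11 ± 0.12 and did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.51). Genes of sensory receptors, which lymphocytes do not use, had an upper quartile level of 5.19 on naive adult, 4.34 on effector and 4.68 on neonatal arrays, and levels up to the value of the group are taken here as its background range. For single sexes it was 5.03 in naive females, 5.41 in naive males, 4.41 in effector females and 4.30 in effector males. Il1r2 in naive cells (3.94) and Il2 in effector cells (3.17) lay in that range, so their values are differences in array signal and the exact change of the transcript is not known, which holds for each gene said below to lie in it.

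Of 16257 genes tested, 5628 differed between effector and naive adult arrays at an adjusted p under 0.05 in limma, 3855 higher and 1773 lower. Of these, 1166 were higher and 389 lower by at least 2-fold. The median difference over all tested genes was 0.03 on the log2 scale as deposited and 0.17 after each array was centred on its median, and the share of higher calls moved from 68.5% to 83.0%, so the balance of higher and lower calls is known only relative to the scaling.

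Gene lists fixed before the data were examined were tested with limma's camera at a preset correlation, and their members were counted at an adjusted p under 0.05 over all genes. Where the count adjusted over the list alone differed, it is given as well. Camera called 14 lists in this comparison. Those for mitosis, DNA replication, sterol biosynthesis, endoplasmic reticulum protein folding and interferon-stimulated genes held with an estimated correlation, and the other 9 did not.

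Cell-cycle genes rose together. All 24 tested mitosis genes rose, with a median of 3.25 (camera adjusted p = 1.3e-30; adjusted p = 0.00573 with an estimated correlation). Top2a, the topoisomerase that untangles replicated DNA, rose by 4.43 ± 0.15, the cyclin Ccnb2 by 4.57 ± 0.17 and the spindle motor Kif11 by 4.27 ± 0.16. All 24 DNA replication genes rose, with a median of 2.62 (camera adjusted p = 1.5e-24; adjusted p = 0.0186 with an estimated correlation). Among them were Rrm2, the small subunit of ribonucleotide reductase, at 3.64 ± 0.15, and Uhrf1, which guides maintenance DNA methylation, at 3.41 ± 0.17. The histone gene H2ac15 rose by 4.45 ± 0.31. In naive cells Top2a, Kif11, Rrm2, Uhrf1 and H2ac15 lay in the background range.

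Of 14 sterol biosynthesis genes, 13 rose, with a median of 1.21 (camera adjusted p = 2.1e-07; adjusted p = 0.0186 with an estimated correlation). The lanosterol demethylase Cyp51 rose by 2.21 ± 0.18 and the isoprenoid enzyme Fdps by 2.10 ± 0.17. In the endoplasmic reticulum folding list 13 of 19 genes rose and 1 fell (15 rose and 1 fell adjusted over the list alone; camera adjusted p = 7.4e-05; adjusted p = 0.0186 with an estimated correlation). Of 13 glycolysis genes, 10 rose, including Pgam1 at 1.69 ± 0.11 and Tpi1 at 1.57 ± 0.16 (camera adjusted p = 3.7e-05; adjusted p = 0.0557 with an estimated correlation). Of 16 genes of fatty acid uptake and storage, 12 rose and none fell over all genes tested (1 fell adjusted over the list alone; camera adjusted p = 1.5e-04; adjusted p = 0.0754 with an estimated correlation). The fatty acid binding protein gene Fabp5 rose by 4.02 ± 0.17 and Dgat2, an enzyme of triglyceride synthesis, by 2.38 ± 0.21. Oxidative phosphorylation genes rose for 12 of 22 members (15 adjusted over the list alone; camera adjusted p = 1.3e-04; adjusted p = 0.192 with an estimated correlation). Of 13 arginine and polyamine genes 6 rose and 2 fell, and the list did not pass (camera adjusted p = 0.148). Slc7a5, a large neutral amino acid transporter, rose by 3.11 ± 0.25 and Arg1, already abundant in naive cells at a level of 10.86 ± 0.17 (SD, n = 6), by 0.59 ± 0.11.

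Interferon-stimulated genes rose for 19 of 22 members, with a median of 1.17 (camera adjusted p = 7.9e-08; adjusted p = 0.0319 with an estimated correlation). Usp18, which restrains interferon receptor signalling, rose by 2.16 ± 0.24 and Bst2 by 1.83 ± 0.26. Among 8 genes of MHC class II presentation 6 rose and 1 fell (7 and 1 adjusted over the list alone; camera adjusted p = 3.7e-04; adjusted p = 0.0557 with an estimated correlation). H2-Ab1, which encodes a class II beta chain, rose by 4.14 ± 0.21, from 6.08 ± 0.57 to 10.22 ± 0.48 (SD, n = 6 each), and H2-Aa by 2.68 ± 0.19. Immediate early genes, which respond within minutes to stimulation, fell for 17 of 22 members and rose for 1 (median -0.79; camera adjusted p = 9.0e-09; adjusted p = 0.0544 with an estimated correlation). Btg2 fell by 1.77 ± 0.14 and Zfp36, which promotes decay of cytokine mRNAs, fell by 1.43 ± 0.17.

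Among 23 ILC2 receptors and surface markers 2 rose and 10 fell (3 and 10 adjusted over the list alone; camera adjusted p = 0.00268; adjusted p = 0.129 with an estimated correlation). Nmur1, the neuromedin U receptor, fell by 2.36 ± 0.22, the IL-7 receptor gene Il7r fell by 1.11 ± 0.14, and Tnfrsf4, which encodes the costimulatory receptor OX40, rose by 2.76 ± 0.26. Klrg1 differed by 0.16 ± 0.18 and Icos by -0.24 ± 0.17, and neither passed. Inhibitory receptors and suppressors of cytokine signalling rose for 7 of 18 members and fell for 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0394; adjusted p = 0.349 with an estimated correlation). Ctla4 rose by 4.11 ± 0.19 and Tigit by 3.48 ± 0.24. Both lay in the background range in naive cells. The call of this list ended after centring, after quantile normalization and without naive male array 3, naive female array 3 or effector female array 1 (camera adjusted p = 0.0583, 0.0507, 0.0517, 0.058 and 0.0528). The lists that follow did not pass. Of 21 cytokines and secreted mediators 9 rose, with Cxcl3 at 3.09 ± 0.20 and Il6 at 2.75 ± 0.22, and 4 fell (camera adjusted p = 0.231). Cxcl3 and Il6 lay in the background range in naive cells. Of 20 ILC2 transcription factors 8 rose, with Irf4 at 3.69 ± 0.24 and Batf at 2.00 ± 0.14, and 1 fell (camera adjusted p = 0.137). Of 18 NF-kB response genes 9 rose (10 adjusted over the list alone) and 4 fell, the atypical inhibitor gene Nfkbid by 1.52 ± 0.15 (camera adjusted p = 0.673). Of 23 migration and retention genes 8 rose and 6 fell, with the sphingosine phosphate receptor S1pr1 up by 2.19 ± 0.24 and the integrin Itgae up by 2.13 ± 0.22 (camera adjusted p = 0.886). Sex steroid and glucocorticoid genes fell for 2 of 9 members (1 adjusted over the list alone; camera adjusted p = 0.122), and fetal-type growth genes rose for 1 of 10 and fell for 1 (camera adjusted p = 0.726). None of 3 Y-linked genes and 1 of 4 X-linked escape genes changed (camera adjusted p = 0.886 and 0.436).

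**Figure D2:**
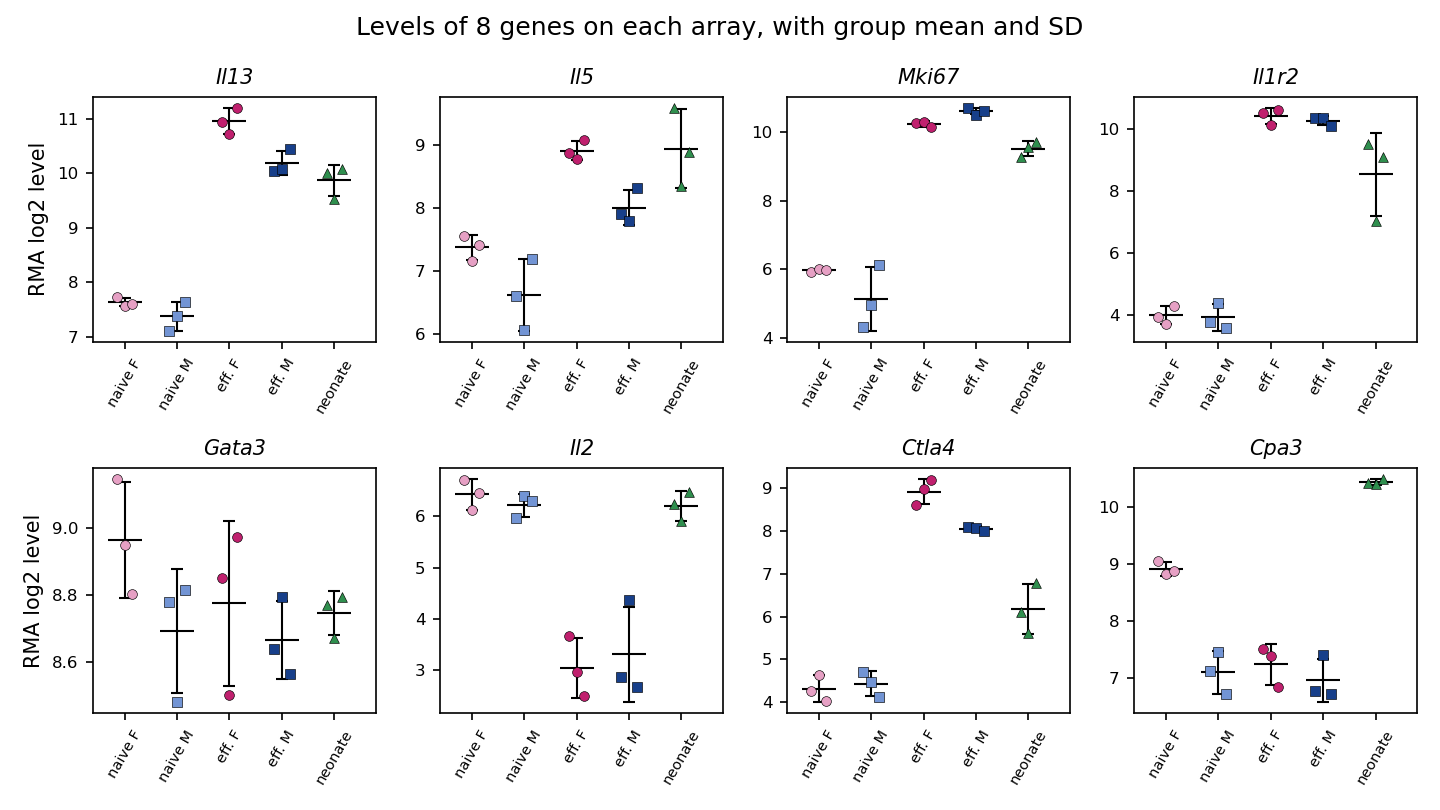
Log2 level (vertical axis, RMA log2 units) of 8 genes on each of the 15 arrays, by group; points are arrays, the long dash is the group mean and the bar 1 SD. Il13, Mki67 and Il1r2 lie higher on effector and neonatal than on naive adult arrays, Il2 lies lower on effector than on the other arrays, and Gata3 did not pass the test in any comparison.

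Markers of other cell types were measured in the same arrays. Endothelial markers fell for 5 of 11 members, led by the phosphatase gene Ptprb, which fell by 1.24 ± 0.21, and the junction gene Cldn5, which fell by 1.06 ± 0.18 (camera adjusted p = 0.00363; adjusted p = 0.215 with an estimated correlation). T cell markers fell for 2 of 10 members, Cd3g by 0.58 ± 0.14 and Cd8b1 by 0.56 ± 0.18 (camera adjusted p = 0.0394; adjusted p = 0.0987 with an estimated correlation). The call of this list ended after quantile normalization, with no filter on dim features, and without naive male array 3 or effector female array 1 (camera adjusted p = 0.117, 0.0851, 0.0569 and 0.0538). Cd8b1 was no longer called after centring (-0.42), after quantile normalization (-0.38), or without naive male array 2 (-0.50), naive female array 2 (-0.42), effector female array 2 (-0.51) or effector male array 2 (-0.47). In effector cells Ptprb lay in the background range, and Cldn5 and Cd8b1 lay in it in both groups. The sensory receptor genes, described below, fell on the same arrays for 203 of 392 members with a median of -0.67, against -0.42 for the endothelial and -0.21 for the T cell list, so a loss of background signal was not excluded for these falls. The other marker lists did not pass. In the B cell list the IgM heavy chain gene Ighm fell by 2.19 ± 0.21 (-0.52 as the mean of its features) and Cd79b rose by 1.00 ± 0.24 among 6 members (1 rose and 2 fell adjusted over the list alone; camera adjusted p = 0.145). Of 6 mast cell and basophil markers 1 fell, Cpa3 by 0.90 ± 0.16 (camera adjusted p = 0.328). NK and ILC1 markers rose for 2 and fell for 3 of 11 members (2 and 4 adjusted over the list alone; camera adjusted p = 0.528), with Il2rb up by 1.56 ± 0.21, and ILC3 markers rose for 1 and fell for 1 of 6, the aryl hydrocarbon receptor gene Ahr by 1.35 ± 0.15 and the lymphotoxin gene Ltb by -1.46 ± 0.18 (camera adjusted p = 0.946). Macrophage markers rose for 1 and fell for 2 of 10 (camera adjusted p = 0.148), neutrophil markers fell for 1 of 7 (camera adjusted p = 0.074), fibroblast markers rose for 1 of 8 (camera adjusted p = 0.335), and none of 12 epithelial markers changed (camera adjusted p = 0.283). Too few eosinophil and erythroid markers were tested for a list test, and Siglecf (-0.37 ± 0.15), Klf1 (-0.27 ± 0.14) and Slc4a1 (-0.27 ± 0.18), all in the background range in both groups, did not pass.

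Probe sets of olfactory and vomeronasal receptor genes, which serve sensory neurons, stood among the largest falls. Of 392 such genes tested, 203 were lower and 4 higher in effector cells, with a median of -0.67, and Olfr1383 fell by 4.29 ± 0.71. All 392 had passed the dim filter, for which any 3 arrays suffice. A silent gene can thus enter through naive arrays where its signal is high, which favours falls in effector cells. No count without the filter is given here. Their mean level was 4.64 ± 0.137 (SD, n = 3) in naive females and 4.94 ± 0.328 (SD, n = 3) in naive males, against 3.89 ± 0.0438 (SD, n = 3) in effector females, 3.87 ± 0.0316 (SD, n = 3) in effector males and 4.20 ± 0.175 (SD, n = 3) in neonates. The largest falls also included Mir101c, a microRNA gene, at -4.08 ± 0.63, and Pla2g10os, an antisense transcript gene, at -4.15 ± 0.57. In effector cells Olfr1383, Mir101c and Pla2g10os lay in the background range.

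**Figure D3:**
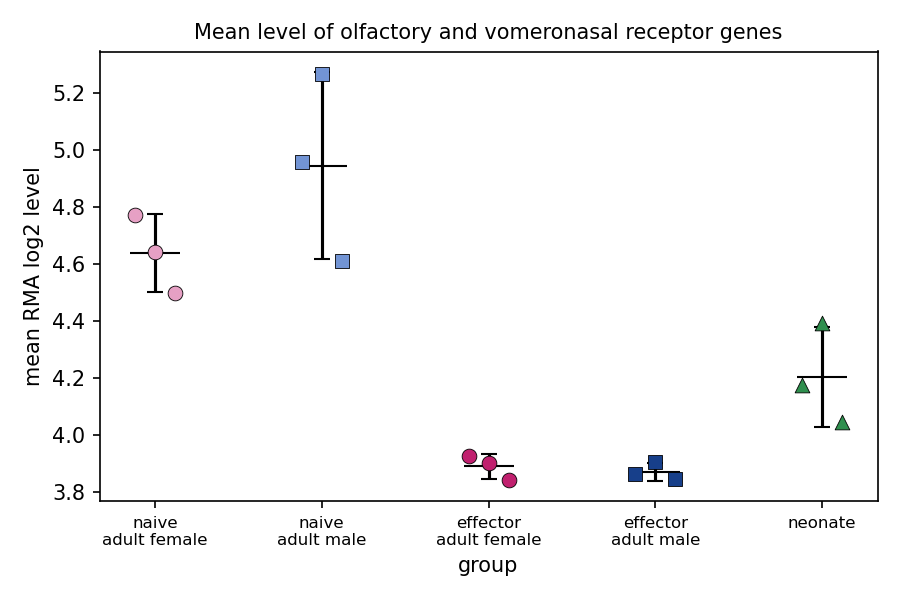
Mean RMA log2 level of the 392 tested olfactory and vomeronasal receptor genes on each array (points), by group, with the group mean (long dash) and 1 SD (bar). Group means were 4.64 and 4.94 in naive adults, 3.89 and 3.87 in effector adults and 4.20 in neonates.

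Il13 was higher in effector than in naive cells by 3.32 ± 0.20 in females and 2.81 ± 0.20 in males (SE, n = 3 arrays per group), Il5 by 1.54 ± 0.30 and 1.39 ± 0.30, Mki67 by 4.26 ± 0.31 and 5.47 ± 0.31, and H2-Ab1 by 3.40 ± 0.29 and 4.88 ± 0.29. Mki67 lay in the background range in naive males. Without the 3 arrays least correlated with the rest, among them naive male arrays 1 and 2, Il5 rose by 0.81 in males and was not called. In females 1663 genes were higher and 613 lower, 2276 in all, and in males 3032 and 1016, 4048 in all, at an adjusted p under 0.05 in limma. Of the 2276, 1812 were also called in males, 1811 of them in the same direction. Across all tested genes, which are not independent replicates, the female and male responses correlated at Pearson r = 0.854 and Spearman rho = 0.783.

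The test of the difference between these responses called 0 genes in limma, with 866 at an unadjusted p under 0.05, and leaving out naive male array 3, naive female array 3 or effector male array 2 gave 8, 1 and 1 calls. Genes called in 1 sex were thus not shown to respond differently in the other. The differences were -1.21 ± 0.44 for Mki67 and -1.48 ± 0.42 for H2-Ab1 (limma adjusted p = 0.87 and 0.71). Without naive male array 3 the difference for Mki67 was -1.71 and passed. The female count dropped to 1358 without effector female array 2 and to 1435 without effector female array 3, and the male count to 2607 without effector male array 3. After centring, higher calls made up 83.9% of 2607 in females (73.1% as deposited) and 86.8% of 4701 in males (74.9% as deposited).

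In naive ILC2s Xist, the transcript that coats the inactive X chromosome, was higher in females than in males by 5.92 ± 0.29 (SE, n = 3 arrays per group), and the Y-linked genes Eif2s3y, Uty and Kdm5d differed by -4.59 ± 0.25, -3.21 ± 0.38 and -3.00 ± 0.23, in the direction the labelled sexes predict. Xist in males and these 3 genes in females lay in the background range, as did Decr2 and Mki67 in males and Dgat2, Srsy and Astx5 in females. Cpa3, which encodes mast cell carboxypeptidase, was higher in females by 1.81 ± 0.23, the prohormone convertase gene Pcsk1 by 1.98 ± 0.22 and Decr2, a peroxisomal enzyme of fatty acid oxidation, by 1.89 ± 0.24. Dgat2 was lower, by -1.70 ± 0.29. The probe sets of Srsy (-3.47 ± 0.42) and Astx5 (-3.68 ± 0.37) belong to multicopy families and are uncertain. Il5 (0.76 ± 0.30), Il13 (0.26 ± 0.20) and Mki67 (0.83 ± 0.31) did not pass. Without naive male array 3, Mki67 was at 1.33 and passed. When only these 6 arrays were fitted, Cpa3, Decr2, Dgat2, Srsy and Uty were no longer called, at the same differences. Dgat2 was also not called with array weights (-1.51) or without naive male array 1 (-1.77), naive male array 2 (-1.71) or naive female array 3 (-1.32), and Decr2 was not called without the 3 least correlated arrays (1.37).

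In all, 34 genes differed in naive cells, 17 in each direction (limma, adjusted p under 0.05), and 1614 at an unadjusted p under 0.05. This count depended on single arrays: it was 18 without naive male array 2, 99 without naive male array 3, and 21, 20 and 16 without naive female arrays 1, 2 and 3, and 8 when only these 6 arrays were fitted. Camera called the Y-linked list lower (3 of 3 members; adjusted p = 4.3e-20; adjusted p = 8.4e-04 with an estimated correlation) and the X-linked list higher (1 of 4 members, 3 adjusted over the list alone; adjusted p = 3.2e-05; adjusted p = 0.179 with an estimated correlation). Endothelial markers and immediate early genes were lower as lists with no member called over all genes (1 immediate early gene adjusted over the list alone; camera adjusted p = 0.00949 and 0.0499; adjusted p = 0.650 with an estimated correlation for both). The sensory receptor genes had a median of -0.23 in this comparison, with 3 called lower and 0 higher. A difference in background signal was thus not excluded for the endothelial markers. The endothelial call ended without naive male array 1, naive female array 2 or naive female array 3 (camera adjusted p = 0.119, 0.0592 and 0.306), and the immediate early call without naive male array 3, naive female array 1 or naive female array 3 (camera adjusted p = 0.415, 0.0705 and 0.166).

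In effector cells 5 genes differed between the sexes: Xist (5.76 ± 0.29), Eif2s3y (-4.89 ± 0.25), Kdm5d (-3.37 ± 0.23), Uty (-3.31 ± 0.38) and Popdc3, a membrane protein gene studied in muscle (-2.18 ± 0.33; limma adjusted p = 0.025), with n = 3 arrays per group. Popdc3 was not called after quantile normalization (-2.00) or without effector female array 1 (-2.27), effector female array 2 (-1.91), effector male array 1 (-2.22), effector male array 2 (-2.01) or effector male array 3 (-2.30). Xist in males and the other 4 genes in females lay in the background range. As a list, mitosis genes were lower in females, with a median of -0.42 and no member called (camera adjusted p = 9.4e-16; adjusted p = 0.0138 with an estimated correlation). MHC class II genes were lower, with a median of -0.52 and 0 members called over all genes, 4 adjusted over the list alone (camera adjusted p = 3.2e-07; adjusted p = 0.0138 with an estimated correlation). Cytokines and secreted mediators were higher, with a median of 0.36 and 0 members called over all genes, 4 adjusted over the list alone (camera adjusted p = 1.8e-04; adjusted p = 0.0124 with an estimated correlation). In limma's fry, which tests whether the genes of a list move on balance in 1 direction, the mitosis and MHC class II lists did not pass (adjusted p = 0.0519 for both). Among single genes, Il5 (0.91 ± 0.30), Il13 (0.77 ± 0.20), H2-Ab1 (-0.83 ± 0.29) and Klrg1 (-0.74 ± 0.25) did not pass over all genes.

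Further lists were called in effector cells with the preset correlation alone, with no member called over all genes. DNA replication (median -0.24) and oxidative phosphorylation (median -0.09) were lower in females (camera adjusted p = 3.2e-07 and 0.0021; adjusted p = 0.168 and 0.421 with an estimated correlation). The oxidative phosphorylation call ended without effector female array 1, effector female array 3 or effector male array 3 (camera adjusted p = 0.0598, 0.0866 and 0.141). Inhibitory receptors (median 0.18; 3 members adjusted over the list alone) and interferon-stimulated genes (median 0.33) were higher (camera adjusted p = 5.7e-07 and 7.6e-06; adjusted p = 0.0637 with an estimated correlation for both). The X-linked list and the Y-linked list held with an estimated correlation (adjusted p = 0.0124 and 5.3e-05 with an estimated correlation). At an unadjusted p under 0.05 in limma, 332 genes differed between female and male effector cells.

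Neonatal ILC2s, taken without treatment, had higher levels of cytokine and cell-cycle genes than naive adult cells. Il1r2 was higher by 4.60 ± 0.39 (SE, n = 3 neonatal and 6 naive adult arrays), Il13 by 2.36 ± 0.17 and Il5 by 1.95 ± 0.26. Mki67 was higher by 3.96 ± 0.27 and Ptgs2, the inducible cyclooxygenase gene, by 3.22 ± 0.30. Vipr2, which encodes a receptor for vasoactive intestinal peptide, was lower and fell by 1.74 ± 0.18, and Flrt2, an adhesion protein gene, fell by 2.84 ± 0.34. Il1r2 in naive adults and Flrt2 in neonates lay in the background range. Gata3 (-0.08 ± 0.15), Klrg1 (-0.17 ± 0.22), Icos (0.60 ± 0.21) and Arg1 (0.32 ± 0.13) did not pass. Icos passed without neonatal array 2 (0.83), and Arg1 with a trended and robust prior.

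Of 16257 genes, 982 were higher and 670 lower in neonates, 1652 in all (limma, adjusted p under 0.05), of which 389 and 243 differed by at least 2-fold. The count was 1031 without neonatal array 1, 935 against female adults alone, 705 with array weights and 676 with only the arrays compared. The labels give no sex for neonates, and both Xist (2.59 ± 0.25) and all 3 Y-linked genes (0.91 to 1.83; camera adjusted p = 8.0e-04; adjusted p = 0.0756 with an estimated correlation) were higher than the mean of the female and male adult groups. Each neonatal array held both Xist (9.44 to 10.29) and the Y-linked Eif2s3y (6.78 to 7.02). Adult males had Xist at 4.82 or less and adult females Eif2s3y at 3.67 or less. These values argue against neonatal samples of a single sex. For samples of both sexes the mean of the log2 levels of females and males is too low a reference. These rises are thus not shown to be changes of expression.

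All 24 mitosis genes rose, with a median of 2.27 (camera adjusted p = 1.8e-39; adjusted p = 0.00203 with an estimated correlation), and 16 of 24 DNA replication genes rose (19 adjusted over the list alone; camera adjusted p = 1.7e-16; adjusted p = 0.0352 with an estimated correlation). Of 21 cytokines and secreted mediators 8 rose, among them Cxcl3 at 3.12 ± 0.25 and Penk, the opioid peptide precursor gene, at 1.20 ± 0.29 (camera adjusted p = 4.1e-05; adjusted p = 0.00845 with an estimated correlation). Of 16 fatty acid genes 8 rose (10 adjusted over the list alone; camera adjusted p = 2.5e-06; adjusted p = 0.0397 with an estimated correlation), with Dgat1 at 1.98 ± 0.36 and Fabp5 at 1.41 ± 0.20. In the arginine and polyamine list 5 of 13 genes rose and 1 fell (8 and 1 adjusted over the list alone; camera adjusted p = 0.00125; adjusted p = 0.0352 with an estimated correlation), with Slc7a5 at 3.05 ± 0.30. These 5 lists were the calls that held with an estimated correlation. Penk was not called without neonatal array 1 (1.10) or neonatal array 3 (0.84). In naive adults Cxcl3 and Penk lay in the background range.

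With the preset correlation alone, camera also called NF-kB response genes (6 of 18 rose, 9 adjusted over the list alone; adjusted p = 1.1e-04; adjusted p = 0.113 with an estimated correlation), with Rel at 1.67 ± 0.25. ILC2 transcription factors rose for 5 of 20 members, 9 adjusted over the list alone, with Irf4 at 2.66 ± 0.29 and Nfil3 at 1.13 ± 0.18 (camera adjusted p = 5.1e-04; adjusted p = 0.113 with an estimated correlation). Glycolysis genes rose for 5 of 13 members, 8 adjusted over the list alone (camera adjusted p = 8.4e-04; adjusted p = 0.102 with an estimated correlation). Endoplasmic reticulum folding genes rose for 3 of 19 members, 7 adjusted over the list alone (camera adjusted p = 0.00411; adjusted p = 0.0712 with an estimated correlation). Sterol genes rose for 4 of 14 members (camera adjusted p = 0.0222; adjusted p = 0.199 with an estimated correlation). Fetal-type growth genes rose for 2 of 10 members, the imprinted zinc finger gene Plagl1 at 2.43 ± 0.42 and the RNA-binding protein gene Igf2bp3 at 0.87 ± 0.22 (camera adjusted p = 0.0189; adjusted p = 0.0756 with an estimated correlation). Igf2bp3 was not called without neonatal array 1 (0.58) or neonatal array 3 (0.77). Plagl1 and Igf2bp3 lay in the background range in naive adults. The sterol call ended without neonatal array 3 (camera adjusted p = 0.121), and the fetal-type call without neonatal array 2 (camera adjusted p = 0.0503). None of 22 interferon-stimulated genes changed (camera adjusted p = 0.171), 1 of 8 MHC class II genes fell (camera adjusted p = 0.637), and of 22 immediate early genes 4 rose and 2 fell (8 and 5 adjusted over the list alone; camera adjusted p = 0.789).

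Markers of other cells were measured on the neonatal arrays too. Mast cell and basophil markers rose for 3 of 6 members (camera adjusted p = 0.00293; adjusted p = 0.113 with an estimated correlation): Cpa3 by 2.43 ± 0.20, the basophil protease gene Mcpt8 by 1.80 ± 0.53 and the tryptase gene Tpsb2 by 0.98 ± 0.19. Fibroblast and matrix markers rose for 3 of 8 members, 5 adjusted over the list alone, with the fibronectin gene Fn1 at 1.42 ± 0.26 (camera adjusted p = 0.0107; adjusted p = 0.0756 with an estimated correlation). Of 12 epithelial markers Sftpc, a surfactant protein gene, rose by 1.98 ± 0.46 and Nkx2-1 by 0.69 ± 0.16 (camera adjusted p = 0.574). In the ILC3 list Il17f rose by 1.77 ± 0.27 and Ahr by 1.44 ± 0.19 (3 rose and 1 fell adjusted over the list alone; camera adjusted p = 0.0623), and in the T cell list Cd3e rose by 1.21 ± 0.25 and Cd28 by 0.81 ± 0.22 (camera adjusted p = 0.19). Endothelial markers fell for 2 of 11 members (median -0.23; camera adjusted p = 0.0599), and 1 of 6 B cell and 1 of 7 neutrophil markers fell (camera adjusted p = 0.637 and 0.745). Of 10 macrophage and 11 NK and ILC1 markers 1 each rose (camera adjusted p = 0.82 and 0.816). Of these genes, Mcpt8 was not called without any 1 of neonatal arrays 1 and 2 (1.50 and 1.24) and the 6 naive adult arrays (1.75 to 1.84), Sftpc without neonatal array 1 (1.72) and Nkx2-1 without neonatal array 2 (0.50). Cd28 was not called without neonatal array 1 (0.45), naive male array 1 (0.76), naive male array 2 (0.78), naive female array 1 (0.81) or naive female array 2 (0.80). With array weights Mcpt8, Sftpc, Nkx2-1 and Cd28 were not called. In naive adults Mcpt8, Tpsb2, Fn1, Il17f and Cd28 lay in the background range, and Nkx2-1 lay in it in both groups. Of the 392 sensory receptor genes, 60 were lower and 3 higher on neonatal than on naive adult arrays.

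**Figure D4:**
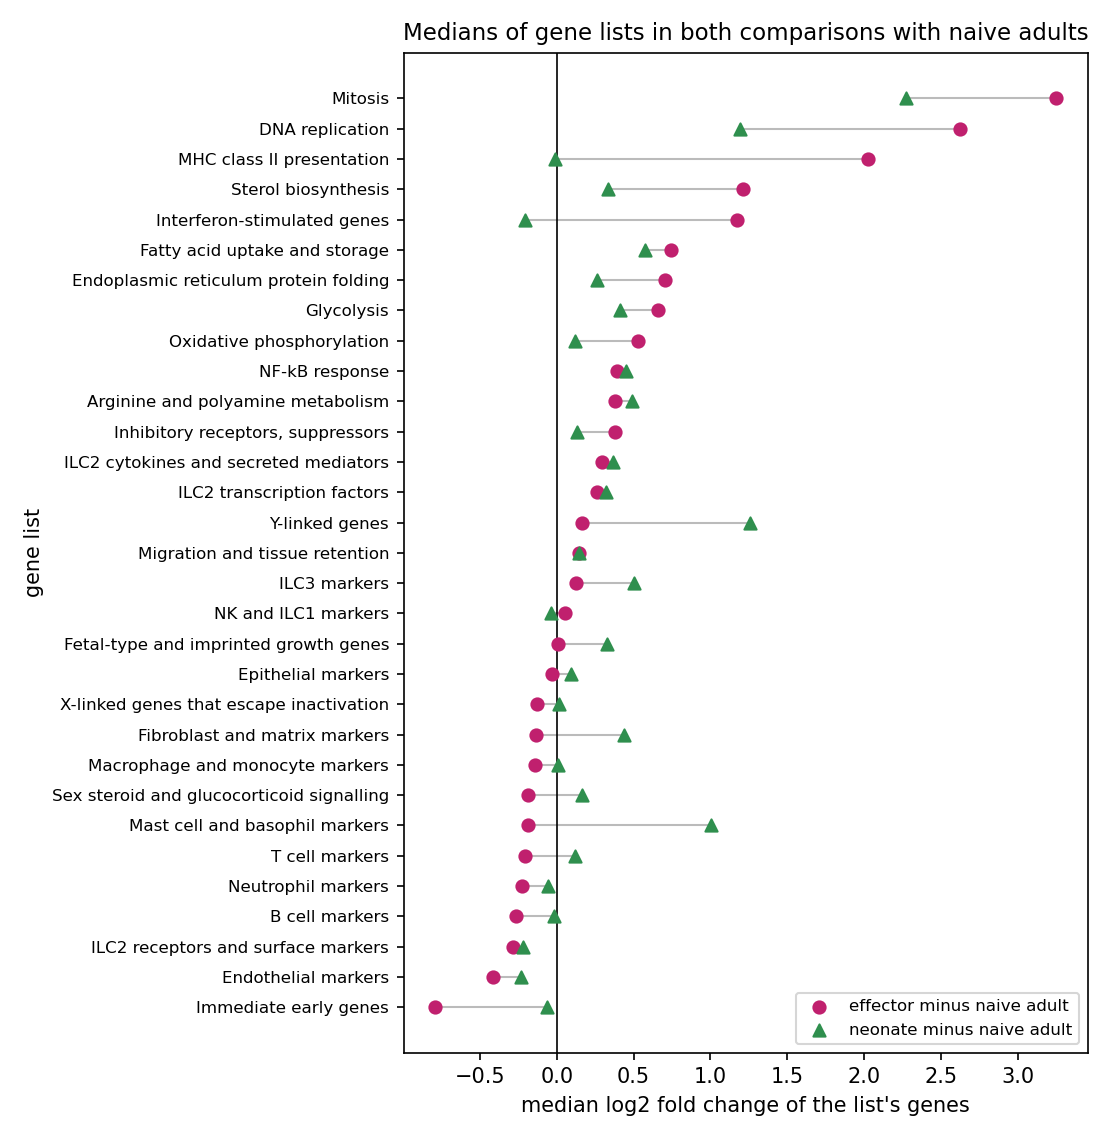
Median log2 fold change (horizontal axis) of the tested genes of each list (vertical axis), for effector minus naive adult (circles) and neonate minus naive adult (triangles); lines join both values of a list. Mitosis had the highest median in both, 3.25 and 2.27, while MHC class II presentation was at 2.03 in effector and -0.01 in neonatal cells.

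Set against effector adults directly, neonatal cells had lower MHC class II, interferon and sterol transcripts. H2-Ab1 fell by 3.48 ± 0.25 (SE, n = 3 neonatal and 6 effector arrays), Usp18 fell by 2.88 ± 0.30, Tnfrsf8, which encodes CD30, fell by 4.36 ± 0.28, and Ifitm3, an interferon-induced antiviral gene, fell by 3.34 ± 0.23. Il2 was higher in neonates by 3.04 ± 0.33, Cpa3 by 3.33 ± 0.20, Kctd12 by 3.16 ± 0.21 and the Notch ligand gene Jag1 by 2.97 ± 0.31. In effector cells Il2 lay in the background range. Il13 was lower and fell by 0.70 ± 0.17, Mki67 fell by 0.90 ± 0.27, and Il5 (0.49 ± 0.26) did not pass. Il13 was not called without neonatal array 2 (-0.54), and Mki67 was not called without neonatal array 1 (-0.78), neonatal array 2 (-0.93), effector female array 2 (-0.89), effector male array 1 (-0.88) or effector male array 3 (-0.90).

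In this comparison 964 genes were higher and 2382 lower in neonates, 3346 in all (limma, adjusted p under 0.05). The count was 2061 without neonatal array 2 and 1942 against female adults alone. After centring, 16.4% of 3687 calls were higher, against 28.8% as deposited. Of 8 MHC class II genes 7 fell and 1 rose (camera adjusted p = 6.0e-06; adjusted p = 0.0229 with an estimated correlation). Interferon-stimulated genes fell for 16 of 22 members, 18 adjusted over the list alone (camera adjusted p = 9.6e-11; adjusted p = 0.0225 with an estimated correlation). Sterol genes fell for 6 of 14, 11 adjusted over the list alone (camera adjusted p = 1.1e-05; adjusted p = 0.0253 with an estimated correlation). DNA replication genes fell for 24 of 24 and mitosis genes for 22 of 24, 24 adjusted over the list alone (camera adjusted p = 4.8e-19 and 1.5e-14; adjusted p = 0.0225 with an estimated correlation for both).

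Immediate early genes were higher in neonates for 11 of 22 members, 12 adjusted over the list alone, with Nr4a2 at 2.09 ± 0.28 and Nr4a1 at 1.64 ± 0.14 (camera adjusted p = 9.6e-11; adjusted p = 0.0253 with an estimated correlation). T cell markers rose for 3 of 10 members, 5 adjusted over the list alone (camera adjusted p = 6.7e-04; adjusted p = 0.0225 with an estimated correlation), and fibroblast markers for 5 of 8 (camera adjusted p = 9.1e-04; adjusted p = 0.0253 with an estimated correlation). Those 8 lists held with an estimated correlation. Of the 392 sensory receptor genes, 32 were called higher and 3 lower in neonates than in effector adults, with a median of 0.30. A difference in background signal was thus not excluded for the T cell, fibroblast, other marker and fetal-type lists called higher in this comparison. With the preset correlation alone, oxidative phosphorylation (9 of 22 fell, 13 adjusted over the list alone) and glycolysis (5 of 13 fell, 6 adjusted over the list alone) were lower (camera adjusted p = 2.1e-04 and 0.0326; adjusted p = 0.189 and 0.208 with an estimated correlation). NF-kB response genes (5 rose, 2 fell) and ILC2 receptors (7 rose, 3 fell; 8 and 3 adjusted over the list alone) were higher, with Nmur1 at 2.09 ± 0.27 (camera adjusted p = 0.00787 and 0.043; adjusted p = 0.208 with an estimated correlation for both). Mast cell markers (2 of 6 rose, 3 adjusted over the list alone; camera adjusted p = 7.7e-04; adjusted p = 0.0808 with an estimated correlation) and fetal-type growth genes (4 of 10 rose; camera adjusted p = 0.011; adjusted p = 0.0546 with an estimated correlation) were higher too. The Y-linked list (3 of 3 rose), ILC3 markers (2 of 6 rose) and sex steroid and glucocorticoid genes (3 rose and 2 fell of 9; 5 and 2 adjusted over the list alone) were called higher and endoplasmic reticulum folding genes (2 rose and 5 fell of 19; 2 and 6 adjusted over the list alone) lower, at camera adjusted p = 0.0022, 0.035, 0.035 and 0.035. None held, at adjusted p = 0.0808, 0.208, 0.0905 and 0.117 with an estimated correlation. For the Y-linked list the limit given above, that neonatal arrays held signal of both sexes, applies here too. Single arrays also ended calls. Without neonatal array 1 the calls of glycolysis, NF-kB response, ILC2 receptor, ILC3 and sex steroid genes ended (camera adjusted p = 0.0902, 0.0865, 0.0796, 0.066 and 0.066). Without neonatal array 3 those of glycolysis, ILC2 receptor, ILC3, sex steroid and endoplasmic reticulum folding genes ended (camera adjusted p = 0.0592, 0.106, 0.0968, 0.0699 and 0.0721), and without neonatal array 2 the folding call (camera adjusted p = 0.0942). The ILC2 receptor call ended without effector female array 2 or effector male array 3 (camera adjusted p = 0.0604 and 0.058), and the ILC3 call without effector female array 2 (camera adjusted p = 0.056).

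The neonatal and effector differences from naive adults were compared across genes, which are not independent replicates and share the 6 naive arrays. Among called genes, 672 were higher in both and 338 lower in both, against 233 and 73.1 for independent lists, while 27 were higher in neonates and lower in effectors and 49 the reverse, against 107 and 159. Il1r2, Il13, Cxcl3, Irf4 and Slc7a5 were among those higher in both. Pearson r was 0.593 and Spearman rho 0.460. In 100 simulations of unchanged groups against shared naive arrays r averaged 0.446 and reached 0.471. Each gene was drawn independently there, while on real arrays many genes can vary together, so this range may be too narrow. The jackknife SE of r over the arrays was 0.122. The simulated groups hold noise and no change, so the simulated r cannot tell how much of the real r shared arrays give. The covariance was 0.191, against a simulated 0.0235, a difference of 0.167. With 3 naive arrays used for 1 difference and the other 3 for the other, r averaged 0.481 and ranged from 0.414 to 0.521 over 20 assignments, and the covariance averaged 0.166. The differences share no array there, so noise of shared arrays is argued against as the whole source of the covariance. A trait common to all 6 naive arrays would remain. Part of the excess in r and in the overlaps may come from the shared arrays.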

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

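The tests of replicate noise, of mast cell, type 2 epithelial and fibroblast RNA and of list levels without single arrays were chosen after the results were seen. The receptor genes were grouped after their values were seen.

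Probe sets of olfactory and vomeronasal receptor genes gave less signal on effector than on naive adult arrays, with a median of -0.67 over 392 genes as deposited, -0.53 after centring and -0.56 after quantile normalization. A shift of all dim probe sets is argued against as the whole cause by 1000 lists of other genes matched on mean level, whose medians lay between -0.161 and -0.0979 in their central 95%. Those lists fell too, by less, so such a shift may be a part of it. The lists and the receptor genes had passed the same dim filter, which can favour silent genes with high signal on naive arrays. Array-wide differences in distribution are argued against as the whole cause, since 140 receptor genes were called lower after quantile normalization, against 203 before. Noise between replicates is not decided by the neonatal arrays, which lay below naive adult arrays by -0.587 as deposited, -0.553 after centring and -0.603 after quantile normalization (exact permutation test, two-sided p = 0.0238 for each, where the smallest p of the 84 splits is 0.0119) and above the effector arrays, whose replicates differed least. That comparison uses the same naive adult arrays, so noise on these would give it as well. The mean receptor level was 4.50 to 5.27 on naive adult and 3.84 to 3.93 on effector arrays, but the genes were grouped after their values were seen. Such noise may contribute. Traces of genomic DNA, amplification of small amounts of RNA and base composition of the probes may contribute too and were not tested, and an effect of IL-33 or of age on these transcripts stays open, also untested.

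In effector cells the mitosis list lay lower and the cytokine list higher in females than in males. Mean mitosis levels were 7.53 to 7.77 on female and 8.04 to 8.10 on male arrays, and mean cytokine levels 6.44 to 6.55 and 6.21 to 6.37, a separation that chance gives each list in 10% of splits of 3 against 3. After a further quantile normalization both lists passed in camera with an estimated correlation (adjusted p = 0.00602 for each). The array medians already averaged 4.472 in effector females and 4.465 in effector males as deposited. That step thus had little to change and is a weak test of array-wide differences in distribution. By the rule set before the results were seen, a camera adjusted p with an estimated correlation of 0.05 or more without 1 array counts for a single array as the source. The mitosis list met that rule. Without effector female array 3 its difference in mean level was -0.32 ± 0.04 (SE) instead of -0.39 ± 0.07. Its adjusted p with an estimated correlation was then 0.0567, against 0.0132 to 0.0483 for both lists over the other omissions. At least 80.2% of the level differences was left without any 1 effector array, a measure chosen after the results were seen. A single array thus stays open as the source of the mitosis call, while most of the level difference remained. An effect of sex and unrecorded differences in timing or handling may also contribute and were not tested.

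Markers of mast cells, epithelium and fibroblasts, of which 6 of 9, 12 of 13 and 8 of 13 passed the dim filter in these ILC2s, were in part higher on neonatal than on naive adult arrays. Cpa3 rose by 2.43, from 8.01 to 10.43, and the 8 other mast cell markers by a median of 0.71, of which Mcpt8, Hdc and Tpsb2 rose by 1.80, 1.02 and 0.98. Sftpc rose by 1.98 to 7.51, while Sftpb, Sftpa1, Sftpd and Nkx2-1 changed by a median of -0.0306, and Fn1 rose by 1.42 to 5.83, while the 12 other fibroblast markers rose by a median of 0.38. These medians decide nothing, because 4 of the 8, 0 of the 4 and 4 of the 12 markers stood over 1 log2 unit above the median receptor gene, at 5.15, in neonates. RNA of mast cells, basophils, epithelium or fibroblasts, expression by the ILC2s themselves, and age may contribute and stay open, and the sort gates that would remove such cells are not given in the sources used here.

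The test of the difference between the female and male responses called lists of genes with the preset correlation, and none of them with an estimated correlation. In camera, mitosis (median -0.59, adjusted p = 1.7e-08), DNA replication (median -0.34, adjusted p = 1.3e-04) and oxidative phosphorylation (median -0.33, adjusted p = 4.4e-04) rose less in females. Inhibitory receptors (median 0.22, adjusted p = 6.8e-06), cytokines and secreted mediators (median 0.21, adjusted p = 0.00192), endothelial markers (median 0.31, adjusted p = 0.00203) and immediate early genes (median 0.14, adjusted p = 0.0214) had the higher difference in females. The sensory receptor genes also had a median of 0.28 in this difference, so a difference in background signal was not excluded for these lists. With an estimated correlation the adjusted p was 0.190 for mitosis and inhibitory receptors, 0.0843 for cytokines, 0.462 for immediate early genes and 0.367 for the other 3, and in fry it was 0.130 to 0.787. No member was called over all genes, while 4 inhibitory receptor genes rose and 1 mitosis gene fell adjusted over the list alone, and leaving out single arrays ended the endothelial call (0.102 without naive female array 3) and the immediate early call (0.306 without naive male array 3, 0.0652 without naive female array 3, 0.168 and 0.0717 without effector female arrays 1 and 3, 0.0557 without effector male array 1).

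Features with no gene symbol carried signal outside the gene tests: of 10337 above the dim filter, 1582 differed between effector and naive adults in limma, 586 higher and 996 lower.

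Chance was made unlikely by other splits of the arrays for effector against naive adults. There the real split called 5628 genes and the highest of the other 99 drawn called 1643, with 1 of 100 splits as large. Chance was also made unlikely for neonates against naive adults (1652 genes against 428, 1 of 84 splits) and against effector adults (3346 genes against 267, 1 of 84 splits). These are the smallest shares that so many splits can give, so chance is not excluded. A batch that follows the groups would give the same result. For the difference of responses the real split called 0 genes in limma, with 866 at an unadjusted p under 0.05, a count that 100 of 100 splits reach by construction, so the splits do not test it, and the highest other called 17. The 10 splits of 3 against 3 are too few for the response of females (2276 genes, highest other 1), the response of males (4048, highest other 1), naive females against males (34, highest other 10) and effector females against males (5, highest other 0).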

How the results depend on the processing

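The fits without the 3 arrays least correlated with the rest, those with receptor genes left out and the lists after quantile normalization were chosen after the data were seen.

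Most counts stayed within 1.5 times their value under the scaling, filter and prior alternatives, and none of the named genes or called lists, nor the relation, reversed. Where a count moved by more, the cause was not tested unless given. A 2-fold threshold, which can only lower counts, gave 1555 genes for effector against naive adults, 1226 in females, 1981 in males, 632 for neonates against naive adults and 1081 against effector adults. Array weights gave 3745 genes for the female response, 1 for the difference of responses, 19 and 11 for the sexes in naive and effector cells, and 705 and 2068 for neonates against naive and effector adults. With only the arrays compared, the sexes differed in 8 genes in naive cells, against 34 with all arrays. Neonates and naive adults differed in 676, against 1652, and the male response had 3471, against 4048. Counts rose from 5 to 8 for the sexes in effector cells and from 2276 to 2886 in females. They rose from 5628 to 6261 for effector against naive adults and from 3346 to 3625 for neonates against effector adults. Fewer arrays alone thus do not explain these changes. The median gene SD was 0.17 in both effector groups, 0.22 in naive females, 0.27 in naive males and 0.31 in neonates. The fit to all arrays pools this spread, whose part was not tested. Without naive male arrays 1 and 2 and neonatal array 2, which leaves 1 naive male array assumed to vary like the other groups, the male response had 2239 genes and the difference of responses 1. Against female adults alone, neonates differed in 935 genes from naive and 1942 from effector adults, and against male adults alone in 1452 and 2501. The relation of neonatal and effector differences was 0.460 as Spearman rho.

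The difference of responses had 1 call at percentile 60 of the dim filter, after centring, with receptor genes left out, with array weights and with the replicate block. That call was Gm20815, a predicted gene whose probe set belongs to a multicopy family and is uncertain, with a difference of 2.88 and an adjusted p of 0.0592 as first fitted and 0.00766 to 0.0468 in these fits. Without the 3 least correlated arrays the call was Igsf6 (2.60, against 1.30 with all arrays). Both genes were chosen after their values were seen.

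Leaving out 1 array at a time gave 4665 to 5735 genes for effector against naive adults, 1358 to 1800 in females, 2607 to 4120 in males, 0 to 8 for the difference of responses, 16 to 99 and 4 to 5 for the sexes in naive and effector cells, 1031 to 1856 and 2061 to 3761 for neonates against naive and effector adults, and r from 0.481 to 0.634 for the relation. Counts moved by more than 1.5 times without effector female array 2 (1358) or 3 (1435) in females, effector male array 3 (2607) in males, neonatal array 1 (1031) against naive and neonatal array 2 (2061) against effector adults. For the sexes in naive cells this held without naive male array 2 (18) or 3 (99) and naive female arrays 1 (21), 2 (20) and 3 (16). For the difference of responses it held without naive male array 3 (8), naive female array 3 (1) or effector male array 2 (1).

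Replicate numbers did not pair the arrays. Residuals of 30 same-numbered pairs correlated at a median of -0.00403 and at most 0.0991, against a median of 0.0111 for differently numbered pairs. With a replicate block the calls were 3793 higher and 1718 lower for effector against naive adults, 1576 and 593 in females, 2961 and 971 in males, 1 and 0 for the difference of responses, 9 and 15 and 1 and 4 for the sexes in naive and effector cells, and 909 and 624 and 893 and 2285 for neonates against naive and effector adults.

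Of 92 list calls over all comparisons, each kept its direction. An adjusted p under 0.05 held for 39 with an estimated correlation, 77 in fry, 86 after quantile normalization, 91 after centring, 83 without the dim filter, 88 without the 3 least correlated arrays and 92 with the replicate block. Among the values of named genes, 354 kept their side of the threshold with array weights, 15 lost and 3 gained a call. After centring 367 kept it and 5 lost it, and after quantile normalization 365 and 7. With only the arrays compared 353 kept it, 18 lost and 1 gained a call.

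Signal over background limits the rest. The receptor genes, which lymphocytes do not use, had a median level of 4.62 and an upper quartile of 5.19 on naive adult arrays, 3.86 and 4.34 on effector arrays, and 4.15 and 4.68 on neonatal arrays, while the medians of the arrays were 4.44 to 4.64. Receptor genes below the dim filter do not enter these levels. A transcript at such a level is not shown to be above background, and a gene below the dim filter is not shown to be absent.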

Other observations

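The 15 gene families below were chosen after the data were seen.

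All 15 aminoacyl-tRNA synthetase genes, whose products charge tRNAs with amino acids, were higher in effector than in naive adults, with a median of 1.17 (camera adjusted p = 4.0e-10; adjusted p = 0.0472 with an estimated correlation). Histone genes rose for 14 of 20 members and fell for 2 (median 1.62; camera adjusted p = 4.7e-06; adjusted p = 0.0472 with an estimated correlation), and kinesins, the microtubule motors, rose for 17 of 37 and fell for 1 (median 0.49; camera adjusted p = 8.0e-06; adjusted p = 0.0472 with an estimated correlation). Mitochondrial ribosomal protein genes rose for 53 of 70 and fell for 1, proteasome subunits rose for 30 of 37, and chaperonin subunits, which fold actin and tubulin, rose for 7 of 8. Their medians were 0.64, 0.68 and 0.86 (camera adjusted p = 7.2e-11, 4.0e-10 and 8.7e-05), and these calls did not hold with an estimated correlation (adjusted p = 0.0734, 0.0573 and 0.0573). Cytosolic ribosomal protein genes rose for 15 of 58 and did not pass (median 0.15; camera adjusted p = 0.0856). These medians stayed above 0 after quantile normalization. Ligands of the TNF superfamily rose for 5 of 8 members (median 0.78; camera adjusted p = 0.0177; adjusted p = 0.0573 with an estimated correlation). Zinc finger protein genes were called lower, with 24 of 315 members up and 39 down (median -0.03, and 0.11 after centring; camera adjusted p = 0.0175; adjusted p = 0.105 with an estimated correlation). Schlafen genes, tubulins, TNF receptors, killer cell lectin-like receptors and regulators of G protein signalling did not pass (camera adjusted p = 0.703, 0.0702, 0.768, 0.0517 and 0.321).

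In neonates against naive adults, kinesins rose for 10 of 37 members and histone genes for 7 of 20 (camera adjusted p = 4.2e-06 and 4.1e-04; adjusted p = 0.0838 with an estimated correlation for both), while 1 of 15 aminoacyl-tRNA synthetase genes rose, 2 of 70 mitochondrial ribosomal protein genes fell and 1 of 37 proteasome genes fell (camera adjusted p = 0.134, 0.134 and 0.380). Zinc finger protein genes rose for 7 and fell for 23 of 315 members (median -0.15; camera adjusted p = 0.00144; adjusted p = 0.0838 with an estimated correlation). Set directly against effector adults, 12 of 15 synthetase genes, 43 of 70 mitochondrial ribosomal protein genes and 21 of 37 proteasome genes were lower, with medians of -0.98, -0.68 and -0.57 (camera adjusted p = 1.3e-09, 3.7e-15 and 1.3e-09; adjusted p = 0.0700 with an estimated correlation for each). Guanylate-binding protein genes, which interferon induces, were lower for 7 of 8 members (median -1.09; camera adjusted p = 9.2e-04; adjusted p = 0.0700 with an estimated correlation). They were also called lower in neonates than in naive adults, where 1 of 8 members fell (median -0.50; camera adjusted p = 0.011; adjusted p = 0.0862 with an estimated correlation), and did not pass in effector against naive adults, where 3 of 8 rose (median 0.27; camera adjusted p = 0.321). Of the other families, none passed between neonates and naive adults. Against effector adults, histone genes (10 of 20 fell), chaperonin subunits (6 of 8 fell), cytosolic ribosomal protein genes (14 of 58 fell), kinesins (12 fell and 1 rose of 37) and tubulins (7 fell and 1 rose of 18) were called lower and regulators of G protein signalling (4 of 13 rose) higher. Their camera adjusted p was 9.2e-04 for the first 3, then 0.0219, 0.0362 and 0.0362, and 0.0700, 0.0850, 0.215, 0.174, 0.0850 and 0.0850 with an estimated correlation. Between female and male effector cells, with no member called, mitochondrial ribosomal proteins, tubulins, kinesins, proteasome and chaperonin subunits were called lower and TNF ligands and regulators of G protein signalling higher in females (camera adjusted p = 1.5e-07 to 0.0121), and none held with an estimated correlation (adjusted p = 0.0763 to 0.359).

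It was asked whether females and males differ in the same genes in naive and in effector cells. With the 7 sex-linked list genes left out, the sex differences correlated across genes at r = 0.0441, and 19 of 100 splits of sex within treatment gave a correlation as far from 0, the highest other being 0.0925. Before the result was seen, a share of 5% or more was to count against a shared sex difference. That bound was dropped after the result was seen, because a correlation over all genes from 3 arrays per group can miss a difference in single genes, so a shared difference stays open.

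It was also asked whether signal from genes that lymphocytes do not use is higher on naive arrays beyond the sensory receptors. In 40 genes of 6 other tissue-restricted families (bitter taste receptors, keratin-associated proteins, beta-defensins, prolactin relatives, major urinary proteins and melanoma antigens) the median difference of effector from naive adults was -0.36, and 1000 lists matched on mean level had medians between -0.189 and 0.00814 in their central 95%. Of the 40 genes 17 were called lower and 1 higher, and the median was -0.22 after centring and -0.23 after quantile normalization. These genes had passed the dim filter too, which can favour falls. The values may reflect a source of signal on naive arrays that is not specific to sensory receptors, a hypothesis for which no cause was tested.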
